A study of Mus musculus with 111 samples.

How the data were processed

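The series holds 111 samples, each a single liver cell sorted as TCRβ, CD4 and IL-17A-GFP positive and turned into a SMART-Seq2 library. Per the submitters' processing notes, reads were quantified with kallisto on mm10; the version, the annotation and the summing of transcripts to genes are not given in the sources used here. The authors deposited the values as TPM, in 1 table of 28987 gene identifiers by 111 cells, with totals of 924449 to 973753 TPM per cell, so the table holds slightly less than each library's full sum. That the unit is TPM was read from these totals and from values that are not whole. TPM keeps no read number, so depth is unknown and no count model was used. Of the identifiers, 27458 matched a symbol in the reference table and 27475 were found in GENCODE M21 (GRCm38), which gave biotypes and coordinates. Pseudogenes took a median of 13.8% of a cell's TPM. No pair of cells had identical values, and the highest Pearson r between 2 cells was 0.61.

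Groups, tests, gene lists, naming rules and most alternatives were fixed before the data were examined. Cells were grouped by the sex and housing temperature in the labels and by the word in the title that reads as a date. The labels do not say what that word marks. Per date, the mean over cells of log2(TPM + 1) was taken for each gene. The difference is the female date minus the mean of the 3 male dates, each date weighted equally. The SD of the 3 male dates is given for some genes. Of 1 date against 3 the smallest one-sided exact p is 0.25, and dates are no animals, so no test was made. Genes were compared if at least 1 TPM in at least 25% of the cells of the female date or, as a mean over the 3 male dates, of the male cells (4091 genes), and counted when the female mean lay at least 1 log2 unit beyond all 3 male means. The same count was made with each male date as the single date. Named genes were the 12 in each direction with the widest gap to the nearest male date, leaving out predicted genes and sex-linked controls, all genes of the share and co-detection rules, up to 4 members of each list with the largest absolute difference, and the 10 genes most variable among cells. Some genes that this rule names are not reported here. Genes of the 4 cells with no receptor gene at 5 TPM, of the 4 cells with both receptor genes and Lyz2, C1qb, Csf1r, Igkc or Alb at 100 TPM, of the low-value background and those that led groups of cells were named after their values were seen.

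The 34 lists were T cell, Th17 program, Th1 and inflammatory, regulatory T cell, naive and recirculating, tissue resident, chemokine receptors, checkpoint, glycolysis, tricarboxylic acid cycle, oxidative phosphorylation, fatty acid oxidation, lipid and sterol synthesis, amino acid, mTOR and Myc, glucocorticoid response, immediate early, heat shock, interferon response, NF-κB and TNF targets, cell cycle, apoptosis, hormone and nuclear receptors, mitochondrial genome, sex check, hepatocyte, macrophage and Kupffer, B cell, NK cell, CD8 T cell, γδ T cell, neutrophil, endothelial, stellate and fibroblast, and erythroid and platelet. Members at 1 TPM or more in at least 10% of cells were used. Hormone and nuclear receptors, NK cell, CD8 T cell, neutrophil, and stellate and fibroblast kept 1 gene, and γδ T cell and erythroid and platelet kept 0, so these lists gave no value. The genes Hmgcs1, Xist, Trdc, Tcrg-V6 and Trdv4 were not analysed here. Each list's median difference was placed among 10000 random lists of the same size, matched in 10 bins of mean expression.

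A gene counted as detected in a cell at 1 TPM or more. Shares have exact Clopper-Pearson 95% intervals, and a share of 0 has the upper limit that 3 cells of the total give, unless the gene was listed at 0 in all cells. Both cover counting error only. Co-detection with Cxcr3 was compared with the count that independence within each date gives, and with 50 genes of similar detection. Cells were clustered with Leiden (resolution 1, 15 neighbours, 15 principal components, seed 1) on 2000 variable genes, date centred. Left out were the genes of the sex check, mitochondrial genome, glycolysis, tricarboxylic acid cycle and oxidative phosphorylation lists. Those of the fatty acid oxidation list and of the amino acid, mTOR and Myc list were left out too. Other metabolic genes could enter. A cluster was named only with at least 3 fixed markers among its top 10 genes. List means were compared between the 2 largest clusters by an exact two-sided sign-flip permutation test over dates with at least 3 cells of each. The fixed plan did not say whether neighbour edges carry weights. A weighted graph was looked at first and gave 7 clusters, and the unweighted graph reported gave 3. No cell was filtered out. No doublet caller was run. Cells with no receptor gene at 5 TPM were counted, which finds no doublet that holds a T cell. Cells with a receptor gene at 5 TPM and Lyz2, C1qb, Csf1r, Igkc or Alb at 100 TPM were counted too, after the values were seen.

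The alternatives fixed at that time were pseudocounts of 0.1 and 10, the log2 of the mean, no detection filter or one of 50%, median-of-ratios rescaling, mitochondrial genes left out, cells with few genes left out, cells matched on genes detected (68 cells, 17 per date), each date left out, cells pooled over dates, detection above 0 or at 5 TPM, resolution 0.5, 1000 variable genes, no date centring and removal of the trend on genes detected. Chosen after seeing the data were protein-coding genes alone, leaving out 3 cells with over 40% of TPM in 10 genes, leaving out the 4 cells with no receptor gene at 5 TPM, centring in expression bins, a filter of 25% of the cells of any date, thinning each date to 21 cells in 100 draws, clusters 1 and 3, seeds 2 to 5 and the weighted graph. The method was tested on simulated data of this comparison (3940 genes, 50 altered per size and direction). All simulated dates were drawn at random from the pooled male cells, so they held no difference between dates. Altered genes came from those at 1 TPM or more in at least 50% of the simulated cells. Of genes made 4-fold higher or lower 50% and 44% passed the limit of 1 log2 unit, of genes made 8-fold higher or lower 76% and 60%, and of unaltered genes 1.66%. Real dates can differ from each other, so 1.66% is no background for the counts of real dates. Of 200 random lists, 3% fell outside the 2.5 to 97.5 percentiles. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, leidenalg 0.10.2, igraph 0.11.9 and scanpy 1.11.5.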

Results

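Messenger RNA was profiled in single T cells from the livers of C57BL/6 mice that carried an IL-17A-GFP reporter, an allele meant to make cells fluoresce when they express the cytokine interleukin 17A. The mice had eaten a high-fat diet for 20 weeks, and cells positive for TCRβ, CD4 and GFP were sorted from the liver. Each library held 1 cell and was made with SMART-Seq2, a full-length protocol that adds no molecular identifiers. Male mice housed at 22 °C gave 78 cells, whose titles carry 3 words that read as dates (21 cells of Jun9, 27 of Aug30 and 30 of Aug31). Female mice housed at 30 °C gave 33 cells, all titled Sept20. Sex, temperature and date therefore divide the cells in the same way and cannot be told apart. The labels name no animal, so each group counted as 1 sample, there was no replicate check of any difference between the groups, and no p-value was computed between them. The spread of the 3 male dates is instead given beside some gene differences as an SD and beside some lists as a range. The values are in TPM, a unit relative to the sum of all transcripts of a cell, and keep no record of read number, so the depth of each library is unknown. A cell had a median of 2716 genes at 1 TPM or more (range 1613 to 4373), and the medians of Jun9, Aug30, Aug31 and Sept20 were 2696, 2679, 2783 and 2764. The 10 highest genes of a cell took a median of 23.1% of its TPM, and 70.9% in 1 cell of Aug31. Mitochondrially encoded genes took a median of 7.27%, and 38.6% in 1 cell of Sept20.

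The sex in the labels was checked first. Tsix (ENSMUSG00000085715; GRCm38 chromosome X, 103431517 to 103484957), an antisense transcript of the X-inactivation centre, reached 1 TPM in 15 of 33 female cells (45.5%, exact 95% interval 28.1 to 63.6) and in 0 of 78 male cells, which allows a share of up to 3.85%. Ddx3y (ENSMUSG00000069045; chromosome Y, 1260771 to 1286629), a Y-linked RNA helicase, reached 1 TPM in 30 of 78 male cells (38.5%, interval 27.7 to 50.2) and in 0 of 33 female cells, which allows up to 9.09%. At least 1 of Ddx3y, Eif2s3y, Kdm5d and Uty reached 1 TPM in 59 of 78 male cells (75.6%) and in 8 of 33 female cells (24.2%, with Eif2s3y in 5 and Uty in 3). At 10 TPM these were 45 male and 2 female cells, and both of those female cells also had Tsix. Without strand information, reads of Tsix and of its overlapping sense gene cannot be told apart, and that sense gene was not analysed here.

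The sort was meant to give Th17 cells, the CD4 T cells that make interleukin 17, and the cells had T-cell transcripts, while Il17f, Il22 and Ccr6 were found in few of them. Il17a (ENSMUSG00000025929; chromosome 1, 20730905 to 20734496) was listed at 0 in all 78 male and 33 female cells. Of 28987 identifiers, 19048 were above 0 in at least 1 cell, and the rest were at 0 in all cells. The table does not show whether such a gene was quantified: Acsl3 and Acads, genes of fatty acid use that many cell types express, were listed at 0 in all cells too. Its neighbour Il17f (ENSMUSG00000041872; chromosome 1, 20777146 to 20790617) reached 1 TPM in 1 cell, and Il22, another Th17 cytokine, in 1 cell. Ccr6, a chemokine receptor of Th17 cells, was detected in 5 cells, and Rora, a nuclear receptor, in 27 (24.3%). Foxp3, the factor of regulatory T cells, was detected in 5 cells and Il10 in 1.

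Transcripts of the T-cell receptor complex and of other T-cell states were commoner. Cd3e, a receptor subunit, reached 1 TPM in 92 cells (82.9% of all cells, interval 74.6 to 89.4), and 105 cells (94.6%) had at least 3 of Cd3e, Cd3d, Cd3g, Trac, Trbc1 and Trbc2 at 5 TPM or more. Cxcr3 (ENSMUSG00000050232; chromosome X, 101731535 to 101734269), a chemokine receptor of inflammatory T cells, was detected in 22 of 78 male cells (28.2%, interval 18.6 to 39.5) and 6 of 33 female cells (18.2%, interval 6.98 to 35.5). Ifng (ENSMUSG00000055170; chromosome 10, 118441046 to 118445892), which encodes interferon γ, was detected in 17 male cells (21.8%, interval 13.2 to 32.6) and 4 female cells (12.1%, interval 3.40 to 28.2). The intervals of the groups overlapped for both genes, which is no test, and a difference was not tested. Cxcr6 was detected in 34 cells, Tnf in 3, Tbx21 in 7, Gzmb in 7 and Csf2 in 5. Cd69, a marker of activated and resident T cells, was detected in 72 cells, and Itgae, an integrin of resident T cells, in 5. Ccr7, which guides naive T cells to lymph nodes, was detected in 34 cells. Among genes of glucose use, Ldha was detected in 97 cells, Pkm in 66, Hk2 in 18 and Slc2a1 in 4, and the proliferation marker Mki67 in 9. Cd4 was at 1 TPM or more in 64.1% of male and 42.4% of female cells, but at 5 TPM or more in 39.7% and 39.4%. These intervals, and the limits above, cover counting error only.

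Markers of other cell types were also present, some at high values in a few cells and some at lower values in many. High values stood in single cells: 4 cells had none of the 6 receptor genes at 5 TPM. Of these, 1 cell of Aug30 carried the macrophage genes C1qb at 6634 TPM and Csf1r at 924 TPM, and 1 cell of Sept20 carried Lyz2, a lysozyme of myeloid cells, at 34443 TPM. The other 2, of Sept20, carried Igkc, an immunoglobulin light chain of B cells, at 19124 and 50296 TPM. In 4 more cells Lyz2, C1qb, Csf1r, Igkc or Alb reached 100 TPM beside at least 4 receptor genes at 5 TPM or more. These were Lyz2 at 36834 TPM, the highest of all cells, and Alb at 225 TPM in 1 cell of Aug31 each, and Igkc at 1567 and 1434 TPM in 2 cells of Sept20. Other markers were not counted in this way, so such cells can be more than 4. Cells of Jun9, a date with none of those above, reached 2509 TPM of the B-cell gene Ighm, 2238 of Cd79b and 427 of the hepatocyte gene Apoa2. Low values stood in most cells: 197 genes lay between 1 and 10 TPM in over 50% of the cells. Lyz2 (ENSMUSG00000069516; chromosome 10, 117277331 to 117282321) reached 1 TPM in 97.4% of male and 39.4% of female cells, Igkc in 93.6% and 42.4%, and the collagen gene Col1a1 in 93.6% and 100%. Shares at 1 TPM can rest on such low values: at 5 TPM or more Csf2 was in 0 of its 5 cells (highest 3.82 TPM), Hk2 in 7 of 18, and Cxcr3 in 21 of 22 male and 3 of 6 female cells. Alb, the albumin gene of hepatocytes, reached 1 TPM in 7 cells and Cyp2e1, a liver cytochrome, in 82. Some markers lay higher in many cells: Cyp2e1 reached 10 TPM in 53 cells (47.7%) and Igkc in 27 (24.3%), and Ighm reached 5 TPM in 29. The natural killer gene Ncr1 was listed at 0 in all cells, Cd8a was detected in 10 cells and the γδ T-cell constant region Tcrg-C1 in 5.

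**Figure D1:**
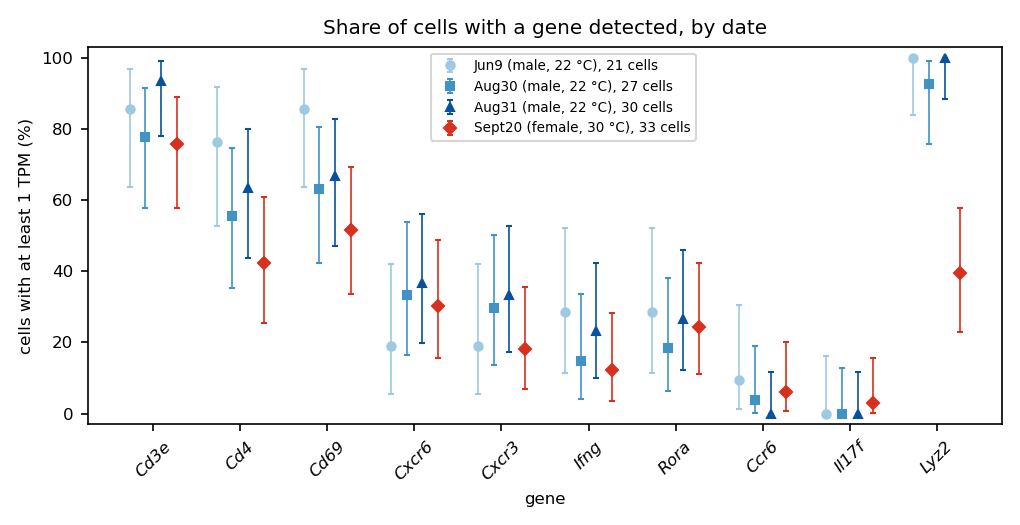
Percent of cells (vertical axis) with at least 1 TPM of each of 10 genes (horizontal axis), by date. Points are shares, bars are exact 95% Clopper-Pearson intervals (counting error only), blue marks are the 3 male dates at 22 °C and the red diamond is the female date at 30 °C. Lyz2 is at 92.6% to 100% in the male dates and 39.4% in the female date.

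The female cells at 30 °C were then compared with the male cells at 22 °C, on the mean over cells of log2(TPM + 1) in each date, a scale that understates the difference of low genes. Leaving predicted genes aside, the gene with the widest gap above all 3 male dates was Vmp1 (ENSMUSG00000018171; chromosome 11, 86583865 to 86683836), which encodes an autophagy membrane protein: its mean was 6.65 in the female date and 3.79 ± 0.23 (SD, 3 dates) in the male dates, a difference of 2.86. It reached 100 TPM in 18 of 33 female cells and 23 of 78 male cells. The widest gap below all 3 male dates was that of Ppp1r15a (ENSMUSG00000040435; chromosome 7, 45522916 to 45526268), a stress-induced phosphatase subunit, at 2.93 in the female date and 5.76 ± 0.22 in the male dates, a difference of -2.83. Irf1 (ENSMUSG00000018899; chromosome 11, 53770014 to 53778374), an interferon-induced transcription factor, lay at 1.89 against 4.09 ± 0.45, a difference of -2.20.

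The other genes with the widest gap above the male dates included the sphingolipid enzyme gene Sptlc2 (difference 1.73), the isocitrate dehydrogenase subunit Idh3a (1.65), the antiviral deaminase gene Apobec3 (1.53), the biliverdin reductase gene Blvra (1.70) and the prion protein gene Prnp (1.85). Lyrm4, an iron-sulfur cluster assembly gene, differed by 2.20, Fmo1 by 1.84, Afmid by 1.74, Lrrc41 by 1.46, Zfp990 by 1.60 and Kif24 by 1.79. Of 78 male and 33 female cells, 14 and 7 reached 100 TPM of Fmo1, and 9 and 4 of Lrrc41. These counts were 7 and 3 for Prnp, 7 and 7 for Kif24 and 1 and 3 for Zfp990. Sptlc2 had 2 and 5, Idh3a 4 and 8, Apobec3 6 and 8, Blvra 2 and 6, Lyrm4 6 and 8, and Afmid 1 and 7. The median of detected male and female cells was 5.71 and 17.9 TPM for Lrrc41, and 4.86 and 12.7 for Zfp990. Below the male dates lay the ribosomal protein genes Rps26 (-2.52) and Rpl19 (-2.22) and the pseudogene Rps13-ps2 (-2.89). Ribosomal genes share reads with near-identical copies, so these 3 values are uncertain. Whether other named genes share reads with copies was not examined. The same side held the myosin light chain gene Myl12a (-2.22), the respiratory complex gene Ndufa3 (-2.23), the NK and T-cell adaptor gene Hcst (-2.18), the splicing factor gene Srsf5 (-2.15), the kinase gene Csnk1a1 (-2.42), Morf4l2 (-2.47) and the ubiquitin ligase gene Cul3 (-1.88). These sizes depend on the scale: with log2 taken of the mean TPM, Csnk1a1 differed by -0.18, Srsf5 by -0.31, Rpl19 by -0.76 and Fmo1 by 0.77, Morf4l2 by -6.44 and Afmid by 4.95.

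**Figure D2:**
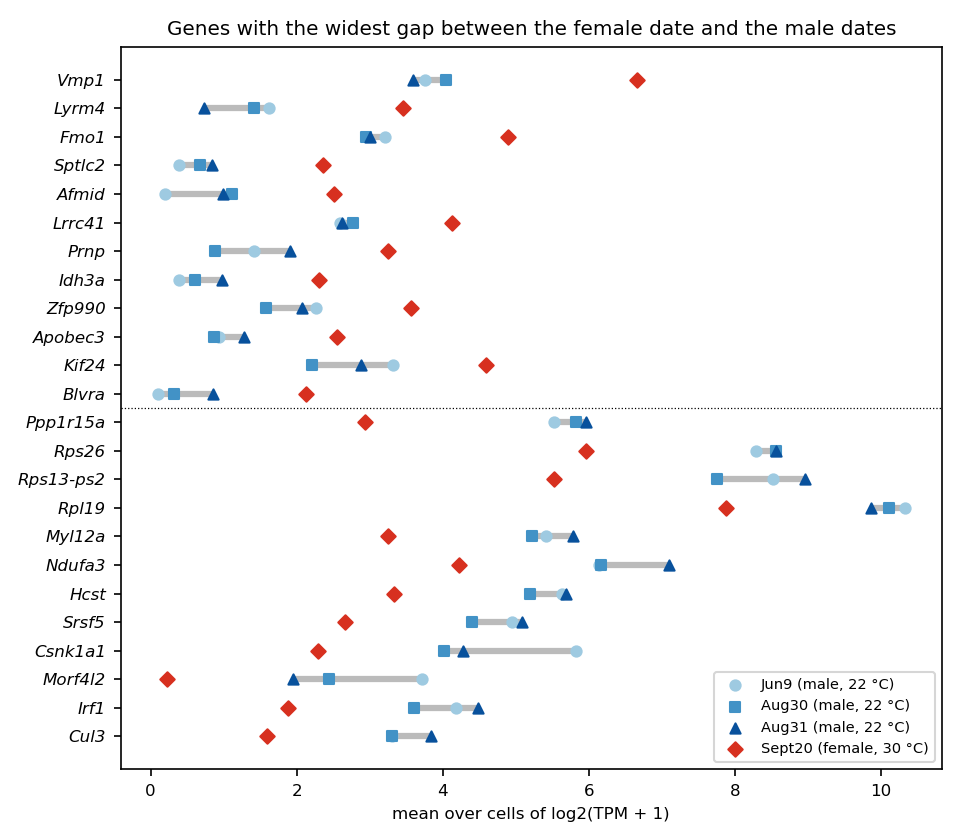
Mean over cells of log2(TPM + 1) (horizontal axis) for the 12 named genes with the widest gap above, and the 12 with the widest gap below, the male dates. Blue marks are the 3 male dates at 22 °C, joined by a grey bar from lowest to highest, and the red diamond is the female date at 30 °C. Vmp1 stands at 6.65 in the female date and Ppp1r15a at 2.93, each outside the grey bar.

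Of 4091 genes detected in at least 25% of the cells of a group, 76 lay at least 1 log2 unit above all 3 male dates and 101 at least 1 log2 unit below them. The female date was the highest of the 4 dates in 29.7% of genes and the lowest in 27.2%, where chance puts any single date highest in 25%. The same count with a male date as the single one gave 127 above and 48 below for Jun9, 34 and 61 for Aug30, and 85 and 13 for Aug31, so that 175 genes set Jun9 apart and 177 set Sept20 apart. The detection filter does not treat the dates alike: a gene of Sept20 alone passes it while a gene of 1 male date alone can fail it. With genes detected in at least 25% of the cells of any date (4964 genes), 206 set Jun9 apart (153 above, 53 below), 45 lay above and 66 below for Aug30, 122 set Aug31 apart and 177 Sept20. Without a filter, 220, 118, 128 and 179 set the dates apart, in the same order. Jun9 has the fewest cells. With every date thinned to 21 cells and the filter on any date, a median of 263.5 genes over 100 draws set Sept20 apart (range 224 to 331), and medians of 192.5, 159 and 198.5 genes set Jun9, Aug30 and Aug31 apart. Sept20 had the most genes in 96 of the 100 draws and Aug31 in 4. Over all cells and with the first filter, Jun9 was set apart by more genes than Sept20 with median-of-ratios rescaling (189 against 162), with protein-coding genes alone (190 against 167) and after centring in bins of mean expression (181 against 167). With a pseudocount of 10, which lowers the weight of low values, only 5 genes remained above and 16 below for Sept20, all of them among the 76 and the 101. Sept20 was then set apart by the fewest genes of the 4 dates, 21 against 49 for Jun9, 22 for Aug30 and 24 for Aug31. Of the 76 and the 101, 43 and 43 were among the genes counted with log2 taken of the mean TPM, 47 and 52 in cells matched on genes detected, and 58 and 80 without the 4 cells that had no receptor gene at 5 TPM. With protein-coding genes alone, a setting that removes all other genes, 46 and 87 of them were counted. With the pseudocount of 10, the 5 were Vmp1, the predicted genes Gm10180, Gm9493 and Gm11032, and 1 identifier without a symbol, the last 4 named after their values were seen. Ppp1r15a, Irf1, Rps26, Rpl19, Hcst, Myl12a, Ndufa3 and Srsf5 were among the 16. The split between higher and lower depended on centring: 42.9% of the 177 genes lay above, and 57.5% (96 above, 71 below) after centring in bins of mean expression. Leaving out Jun9 gave 126 above and 169 below, leaving out Aug30 215 below, and leaving out Aug31 145 above.

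The heat-shock genes, whose products fold proteins, stood lowest among the lists of gene functions. The median difference over 11 of them was -1.15, with 7 below and 1 above all 3 male dates, and none of 10000 random lists matched on expression lay as low (percentile 0). Hsp90ab1 (ENSMUSG00000023944; chromosome 17, 45567775 to 45573271) differed by -2.19, Dnaja1 by -1.83 and Hspa1b by -1.26. Hsp90aa1 differed by -1.20 within the range of the male dates. A male date set against the other male dates gave medians from -0.92 (Aug30) to 0.31. With a pseudocount of 10 the female median was -0.56. With log2 taken of the mean TPM it was -0.69, with Hsp90ab1 at -0.24 and Dnaja1 at -0.30. Immediate early genes, which are induced within minutes of stimulation, had a median of -0.27 (percentile 13.6, 5 of 14 below), with Btg2 at -1.34, Egr1 at -1.10 and Zfp36 at -1.09.

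T-cell state lists pointed in several directions. Genes of inflammatory Th1 cells had a median of -0.44 (percentile 5.96, 6 of 8 below all male dates and 1 above): Nkg7, a cytotoxic granule gene, differed by -1.35, Cxcr3 by -1.12 and the chemokine gene Ccl5 by -0.83, and Il12rb2 by 0.53. This list's median was 0.36 when log2 was taken of the mean TPM, a scale on which the median of all genes was 0.14. Genes of naive and recirculating T cells had a median of -0.73 (percentile 3.94, 5 of 9 below): Tcf7 (ENSMUSG00000000782; chromosome 11, 52252371 to 52283014), a transcription factor of naive and memory T cells, differed by -2.30, Dgka by -1.26, Il7r by -0.92 and Satb1 by -0.82, and Jun9 against the other male dates gave a median of -1.19. SDs over the male dates were 0.70 for Tcf7, 0.95 for Dgka, 0.22 for Il7r and 0.65 for Satb1. With log2 taken of the mean TPM, Tcf7 differed by -0.84. The 4 measurable Th17 genes had a median of 0.34 (percentile 87.9), with Maf at 1.10 and Rora at 0.21 above all male dates, and Batf at 0.48 and Stat3 at 0.13 within their range. Genes of regulatory T cells had a median of 0.68 (percentile 99.3) and a mean of 0.09. Of its 5 genes Tnfrsf4 (1.22) and Ikzf2 (0.68) lay above all male dates, Tnfrsf18 (-2.08) lay below them, and Ctla4 (0.71) within their range. Without Aug30 this median was 0.06, and without a filter on detection -0.08. For the same list, Jun9 against the other male dates gave a larger median, 0.87. Chemokine receptors had a median of -0.49 (percentile 6.21, 6 of 8 below), with Ccr2 at -0.95 and Cxcr4 at 1.27.

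The series is about metabolism in these cells, and the metabolic lists were compared next. Genes of glycolysis had a median of -0.25 (percentile 16.9), with 7 of 15 below all male dates and none above. Ldha (ENSMUSG00000063229; chromosome 7, 46841475 to 46855627), the lactate dehydrogenase subunit, differed by -1.77, Gpi1 by -1.16, Eno1 (ENSMUSG00000063524; chromosome 4, 150236721 to 150248879) by -1.12 and Ldhb by -0.92. SDs over the male dates were 0.43 for Ldha, 1.54 for Gpi1, 0.22 for Eno1 and 0.30 for Ldhb. Gpi1 stood at 5.24 in Jun9, 2.61 in Aug30, 2.54 in Aug31 and 2.31 in the female date. The glycolysis median was 0.11 in cells matched on the number of genes detected, -0.02 after centring in expression bins, and -0.08 without Jun9, -0.48 without Aug30 and -0.41 without Aug31. Genes of oxidative phosphorylation went both ways, with 14 of 59 above and 16 below all male dates and a median of 0.06 (percentile 96.2), or -0.20 in matched cells: Atp5j differed by -2.14, Cox4i1 by -1.45, Cox7c by -1.36 and Ndufb7 by 1.47. SDs over the male dates were 0.89 for Atp5j, 1.13 for Cox4i1, 0.74 for Cox7c and 0.39 for Ndufb7. The tricarboxylic acid cycle had a median of 0.01 (5 of 19 above, 2 below), with Idh3a at 1.65, Pdhb at 1.41, Idh3g at -1.42 and, within the range of the male dates, Sdha at -1.27. Fatty acid oxidation had a median of -0.22 (2 of 15 above, 5 below), with Etfa at 0.94 and Acaa2 at -0.78. The amino acid, mTOR and Myc list had a median of 0.25 (3 of 9 above, none below), with Myc at 0.63 and, within the range of the male dates, Slc38a2 at 0.47, and lipid and sterol synthesis a median of -0.02.

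Of the remaining lists, interferon response had a median of -0.29, NF-κB targets -0.26, tissue residency -0.22, glucocorticoid response -0.17, apoptosis -0.14, cell cycle 0.21, checkpoint receptors 0.22, mitochondrially encoded genes 0.11 and T-cell genes -0.12. Lists of other cell types gave -0.81 for macrophages (Lyz2 and Cd68, of whose 89 and 14 cells 39 and 3 reached 5 TPM), -0.16 for hepatocytes, -0.14 for B cells and 0.01 for endothelial cells. Over the 27 lists with at least 2 usable genes, 2 medians lay in the lowest 2.5% of their random lists (heat shock and the sex-linked genes, at -1.26). Another 1 lay in the highest 2.5% (regulatory T cells). Lists of genes drawn at random would give 1.35 in all. The sex-linked list is a control set by the sex of the mice, and genes of a list can vary together. The counts can therefore not be judged against 1.35. Random lists are a description of these libraries and no test between groups.

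**Figure D3:**
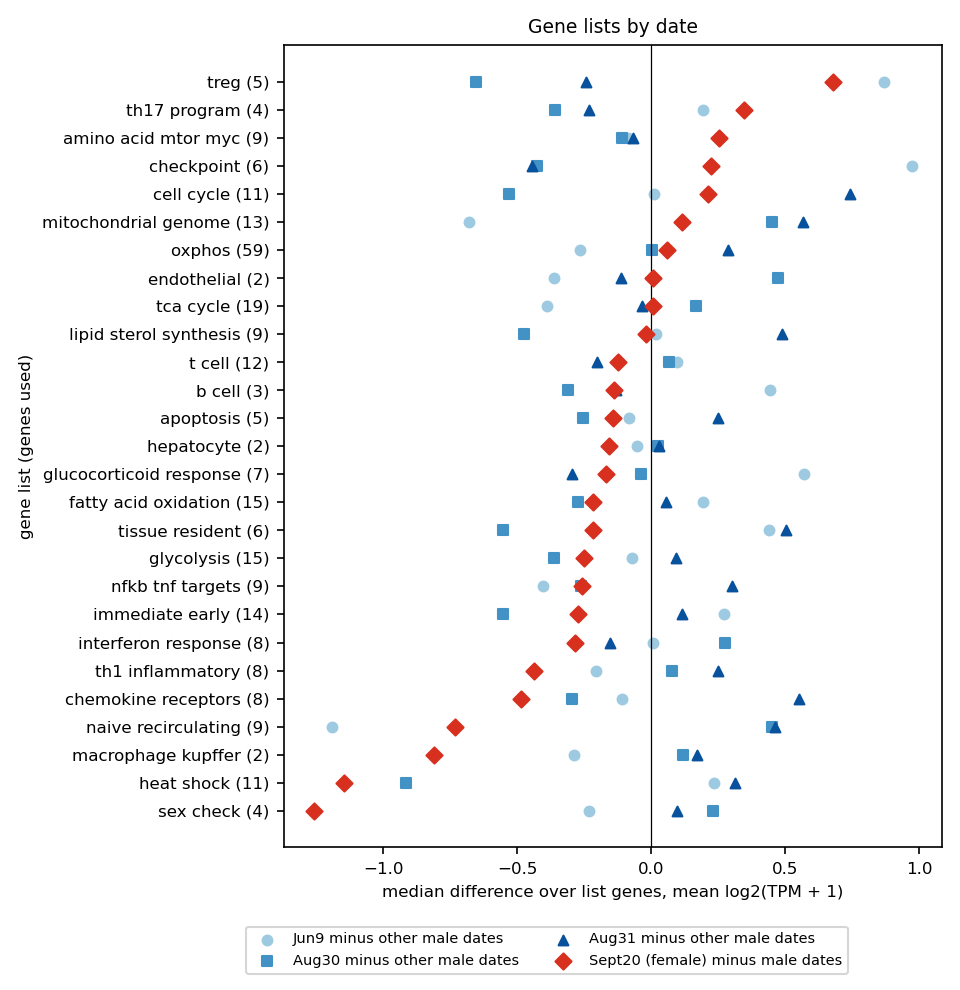
Median difference over the genes of each list on mean log2(TPM + 1) (horizontal axis) for the 27 lists (vertical axis, genes used in brackets). The red diamond is the female date minus the mean of the 3 male dates, and blue marks are each male date minus the mean of the other male dates. The heat-shock diamond lies at -1.15, beyond the male dates (-0.92 to 0.31). Also beyond them lie sex check (-1.26 against -0.23 to 0.23) and macrophage (-0.81 against -0.29 to 0.17). So do the amino acid, mTOR and Myc list (0.25 against -0.11 to -0.07) and Th1 (-0.44 against -0.21 to 0.25). The Th17, chemokine receptor, interferon response and hepatocyte diamonds lie beyond the male dates as well. The other diamonds lie within the range of the blue marks.

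Cxcr3 marks inflammatory T cells, and the genes found in the same cells were counted over all cells. Cxcr3 and Ifng were detected together in 11 cells where independence within each date gives 5.39, a ratio of 2.04 (exact 95% interval 1.02 to 3.65, counting error only). Over 50 genes detected about as often as Ifng, the ratio with Cxcr3 had a median of 1.13, and its highest 2.5% lay above 1.76. The ratio was 1.35 for Cxcr6, 1.22 for Nkg7, 1.32 for Hk2 (7 of its 18 cells at 5 TPM or more), 1.12 for Pkm (ENSMUSG00000032294; chromosome 9, 59656368 to 59679375), 1.0 for Ldha and 0.99 for Ccl5, each inside the range of its matched genes. Il17f, Tnf, Tbx21, Ccr6, Gzmb and Foxp3 shared at most 1 cell with Cxcr3, too few to compare, and Il17a could not be compared. With any value above 0 taken as detection, the ratio for Ifng was 1.06.

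Cells were also grouped by expression, with date centred out and without the genes of the metabolic lists compared here. The aim was to ask whether metabolic genes differ between groups of these cells. Other metabolic genes, such as those of lipid and sterol synthesis, could enter the grouping. The groups held 42, 35 and 34 cells. Group 1 had 10, 13, 12 and 7 cells of Jun9, Aug30, Aug31 and Sept20, and group 2 had 6, 6, 8 and 15. Group 3 was named naive or recirculating-like from Satb1, Lef1 and Il7r among its top 10 genes, and groups 1 and 2 stayed unnamed. S100a6, Lgals1 and S100a4 led group 1, and Trbj2-5, Ltbp1 and Limk2 led group 2. Genes of oxidative phosphorylation were higher in group 1 than in group 2 in 4 of 4 dates, by 1.66 ± 0.89 (SD, 4 dates) on log2(TPM + 1). Glycolysis was higher by 1.09 ± 0.61, the tricarboxylic acid cycle by 0.82 ± 0.41 and fatty acid oxidation by 0.54 ± 0.34, each in 4 of 4 dates. Some settings gave fewer dates: glycolysis was higher in 3 of 4 without date centring (0.80, Jun9 -0.52, exact permutation p = 0.25) and with seed 2 (0.80, Jun9 -0.13, p = 0.25), and fatty acid oxidation in 2 of 3 with seed 3 (0.38, p = 0.50). With the settings first named, for each of these 4 lists the exact two-sided sign-flip permutation test gave p = 0.13 over 4 dates, the smallest p that 4 dates allow. The groups were formed over all dates at once, from genes that can vary with these lists, so the 4 dates are no independent support. The amino acid, mTOR and Myc list differed by 0.15 ± 0.57, higher in 2 of 4 dates (exact permutation p = 0.75). Other lists differed between groups 1 and 2 too, given as the distance from the date mean. T-cell genes stood at 0.56 and -0.71, Th1 genes at 1.16 and -0.45 and tissue residency at 0.88 and -0.45. Regulatory T-cell genes stood at 0.67 and -0.13, Th17 genes at 0.58 and -0.30 and cell cycle at 0.44 and -0.19. Naive and recirculating genes (-1.13 and -0.16) and mitochondrially encoded genes (-0.24 and 0.06) were lower in group 1. The median numbers of genes detected were 2760.5 and 2601. With the trend on genes detected removed, oxidative phosphorylation differed by 1.28 and glycolysis by 0.77. Leaving out the cells with no receptor gene at 5 TPM left 41 cells in group 1 and 32 in group 2. Oxidative phosphorylation then differed by 1.59 and glycolysis by 1.09, each higher in 4 of 4 dates. The grouping itself depended on its settings, with 4 groups under each of 4 other random seeds and 7 with a weighted neighbour graph.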

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

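The alternatives of protein-coding genes, concentrated cells, cells with no receptor gene at 5 TPM, expression bins, a filter on any date, thinning, clusters 1 and 3, seeds and graph weights were chosen after seeing the data. The counts of genes above and below all male dates, 76 and 101, were 216 and 304 with a pseudocount of 0.1, 5 and 16 with 10, 269 and 244 for the log2 of the mean, 45 and 65 with a 50% filter, 161 and 153 in matched cells, 205 and 318 with cells pooled, and 129 and 131 thinned to 21 cells per date. Leaving out 1 male date gave 112 to 145 above and 143 to 215 below. Fewer dates, a tighter filter and a larger pseudocount change these counts by construction; for the other settings the cause was not tested. Each of the 24 named genes kept its sign in every setting, but not its size: for the log2 of the mean, Csnk1a1 (-2.42) was -0.18, Srsf5 (-2.15) -0.31 and Rpl19 (-2.22) -0.76.

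The Th1 median (-0.44) was -0.83 with a pseudocount of 0.1, -0.20 with 10, 0.36 for the log2 of the mean and -1.09 with the 50% filter. Glycolysis (-0.25) was -0.42 with a pseudocount of 0.1, -0.45 with the 50% filter, 0.11 in matched cells, -0.024 centred in bins and -0.48 to -0.084 with 1 male date left out. Heat shock (-1.15) was -0.56 with a pseudocount of 10. The Th17 list (0.34) was 1.03 for the log2 of the mean and 0.61 with the 50% filter. Oxidative phosphorylation (0.06) was -0.20 in matched cells. Regulatory T-cell genes (0.68) reversed to -0.078 with no filter and lay between 0.063 and 0.75 with 1 male date left out. Shares with any value above 0 were 87.2% male and 66.7% female for Cxcr3, and 56.4% and 30.3% for Ifng. Between clusters 1 and 2 the amino acid list (0.15) reversed to -0.021 with the trend on genes detected removed, to -0.048 between clusters 1 and 3, and to -0.034 and -0.032 with seeds 3 and 4, and lay between -0.081 and 0.33 with 1 date left out. Glycolysis was higher in 3 of 4 dates without date centring and with seed 2 (p = 0.25), and fatty acid oxidation in 2 of 3 with seed 3 (p = 0.50). The cause was not tested.

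Of the values of the main results, 224 stayed the same, 37 moved and 6 reversed. Of the values of the rest, 383 stayed the same and 112 moved. A gene count stayed the same within a fixed factor of the main count, and a share or co-detection ratio within its exact interval. A list median did so within the SD of the male dates, and a tested value by keeping its direction and side. Leaving out cells with few genes removed 0 cells, so it says nothing, and the weighted graph gave no value because fewer than 2 dates held enough cells. A 50% filter left some lists without genes. No paired analysis was possible because the groups share no animal and were not tested; clusters were compared within dates. Unknown depth and the number of cells limit every share, and values of a few TPM limit each difference of a low gene.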

Other observations

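All tests in this part were chosen after the result was seen.

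The genes that varied most among cells within a date were T-cell receptor β joining segments: Trbj2-7 (45.9% of cells at 1 TPM or more), Trbj2-1 (42.3%), Trbj2-4 (32.4%), Trbj2-5 (28.8%) and Trbj1-1 (27%). The vesicle transport gene Arf4 (72.1%) and the predicted genes Gm14287, Gm17181, Gm13577 and Gm11966 made up the rest of the 10. Principal component 1 held 5.37% of the variance. In group 1 of the cells, Cxcr3 was detected in 22 of 42 cells and Ccr6 in 5 of 42, and in group 2 in 4 of 35 and 0 of 35; these genes were open to the clustering, so the shares describe it.

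Il17a was listed at 0 in all cells of a sort for an Il17a reporter. A transcript missing from the quantification could give this, and it stays open: Acsl3 and Acads, 9.09% of the fatty acid oxidation list, were also at 0 in all cells, but low expression gives 0 as well. Over all 28987 identifiers, 19048 were above 0 in at least 1 cell. Whether cells without an active Th17 program passed the gate is not reported here and stays open. The labels do not say how the reporter allele alters the Il17a transcript, and short-lived mRNA behind a lasting fluorescent protein was not tested.

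The heat-shock list was lower in the female date (-1.15). A trend of the difference with mean expression is argued against as the whole cause, since the median stayed at -0.90 after centring in expression bins, against an SD of 0.46 over male dates. A difference between days stays open, because the male date Aug30 lay at -0.92 against the other male dates. A weaker response to tissue handling in the female date than in the male dates would leave immediate early genes lower too. Their list stood at percentile 13.6, which does not decide. Sex and housing temperature remain among the open explanations, since each is the same split as the date.

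Genes foreign to T cells lay at 1 to 10 TPM in most cells: Slitrk2, Frmpd3, Ebf1, S100b and Col1a1 were among the 18 genes of any kind in that range in over 90% of cells. RNA of stellate cells or fibroblasts in every well is argued against, since Col1a2, Sparc and Bgn, abundant in them and above 0 in some cells, reached 1 TPM in at most 12.6% of cells while Col1a1 did in 95.5%. RNA of macrophages that express C1q genes is argued against in the same way, with C1qa, C1qb and C1qc at 1 TPM in at most 1.80% of cells while Lyz2 was in 80.2%. RNA of other myeloid cells stays open, since Tyrobp (highest 9002 TPM) was at 1 TPM or more in 55.9% of cells and Cd68 in 12.6%. Reads given to the wrong gene could account for the 197 genes in over 50% of cells; without reads this was not tested, and no biological explanation, such as expression by the T cells themselves, was tested.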
